A study of Zea mays with 12 samples.

How the data were processed

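Embryos of the maize inbred lines B73 and Mo17 were taken from seeds imbibed for 2 h at 25 °C or 10 °C, with 3 biological replicates in each of the 4 groups, per the labels. Per the labels' protocols, polyadenylated RNA was selected from total RNA, libraries were made with a method that keeps the strand by dUTP, and fragments were read in pairs on an Illumina NovaSeq. The submitters' processing notes name cutadapt 1.9, HISAT2 2.0.4, StringTie 1.3.4d, edgeR and DESeq2 and the genome build B73 RefGen_v4, with no role or order. Whether the counting used the strand is not given in the sources used here.

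A single table served all comparisons. Per the file headers it holds, for each gene and library, a count and an FPKM (fragments scaled to gene length and library size), both made by the authors before deposit, with the gene's position, strand and annotation. It covers 99 genes, in alphabetical order of symbol, and other genes were not analysed here. No column of per-sample values was left unused. The deposited counts are whole numbers, but none of them is 1 or 2, the smallest above 0 is 3, and the value 4 occurs 19 times, so that a single fragment appears to be worth several counts, as in counts derived from coverage. No counting intervals or floors are therefore given, and a gene without counts is described as listed at 0. The deposited FPKM equals the count divided by a constant of the gene and a constant of the library, within 0.207% over 47 genes with an FPKM of at least 5 in all libraries. This ratio gave the relative depth of each library, 0.817 to 1.08. The total number of fragments is unknown, and FPKM was not compared between genes. Reads of near-identical genes could have been divided between them by the authors' counting.

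Before the data were examined, limma on log2(FPKM + 1) had been fixed as the test for a table without counts and the edgeR quasi-likelihood test for a table with counts. Since the table holds counts, the edgeR test was used, and limma became an alternative. edgeR 4.0.16 in R 4.3.3 was run on the counts with library sizes proportional to the relative depth, without TMM factors, because 76 genes are too few to assume that most did not change. 1 model of 4 group means over all 12 libraries shared its estimate of the spread. Genes with an FPKM of at least 1 in at least 3 of the 12 libraries were kept, which left 76. Tests were 2-sided, and p-values were adjusted by Benjamini-Hochberg over the 76 genes with a threshold of 0.05. The contrasts were 10 °C against 25 °C in each line, Mo17 against B73 at each temperature, and the interaction, and the average of both cold contrasts was added after the data were seen. Standard errors were derived from the test, as the log2 change refitted without a prior count divided by the square root of the F statistic. The log2 changes beside them are from the fit with edgeR's default prior count. Normalized counts are counts divided by relative depth. The p-values set each difference against the spread between the 3 biological replicates within a group, estimated over the 4 groups with information shared between genes.

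The rule for genes to name, fixed before the data were examined, took genes past the threshold whose libraries did not overlap and whose mean FPKM was at least 1 in the higher group. It took the 10 largest changes per direction with temperature, the 5 largest per direction between the lines, and up to 4 members of each list with the smallest p. Other genes named were chosen after their values were seen, and the result of 1 gene that the rule took is not reported here. 23 gene lists were matched by symbol or description. 2 of them, hormone signalling and mitochondrial respiration, had at least 5 tested members and were tested with limma's camera (preset correlation 0.01, and estimated) and fry (limma 3.58.1). KEGG and GO terms of the table were tested by Fisher's exact test where they had at least 10 tested members, and, added after the data were seen, by camera and fry where they had at least 5. Chromosome numbers were assigned from the transcripts of 91 genes found in the RefSeq gene table of the later NAM assembly of B73, whose coordinates were not used, and positions are those of the deposited table.

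The procedure was tested on simulated data, 20 sets of 76 genes drawn with the means and spread of the cold comparison in B73. It recovered 31.9% of genes changed 1.5-fold, 80.3% of those changed 2-fold and 95.5% of those changed 4-fold, and 4.9% of the calls were false. Changes of 2-fold or less at 10 °C can thus be missed. The values were drawn independently from the distribution that the test assumes, and no library was made to stand apart, so the rates in the real data may be worse. The alternatives were other pseudocounts, filters, scalings and variance models, replicate number as a block, each library left out in turn, fits of the 6 libraries compared, and, added later, limma on log2(FPKM + 1), TMM factors and DESeq2 1.42.0.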

Results

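RNA from maize (Zea mays) seed embryos was sequenced in 12 libraries. The embryos came from 2 inbred lines, B73, which the labels call resistant to low temperature, and Mo17, which they call sensitive. Seeds took up water in germination paper at 25 °C, the normal condition, or at 10 °C, and were sampled at 2 h. Each line and temperature gave 3 biological replicates, so the study holds 4 groups of 3. The gene table used here covers 99 genes whose symbols run alphabetically from a2 to ARF16, with a count and an FPKM for each gene in each library, and 76 of these genes passed the filter on low values. Counts over the 99 genes summed to 576807 to 769480 in B73 libraries and to 981557 to 1299983 in Mo17 libraries. These sums are not library totals. The depth of the libraries relative to each other, recovered from the ratio of count to FPKM, ran from 0.817 in B73 25 °C replicate 1 to 1.08 in B73 10 °C replicate 2. Absolute depth is unknown, and the counts below are normalized, which means divided by that relative depth. Libraries of the same group correlated at 0.969 to 0.997 over the tested genes, libraries of 1 line at the other temperature at 0.967 to 0.995, and libraries of different lines at 0.874 to 0.918 (Pearson r of log2(FPKM + 1), across genes, which are not independent replicates).

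The first question was which genes responded to 10 °C in B73. ald1, which encodes cytoplasmic fructose-bisphosphate aldolase, an enzyme of glycolysis, fell from 35643 ± 2738 normalized counts at 25 °C to 17308 ± 3871 at 10 °C (mean ± SD, n = 3 each), a 2.06-fold decrease. Its log2 change was -1.04 with a standard error of 0.22, and all 3 libraries at 10 °C lay below all 3 at 25 °C. The next gene in order of p was adh1, an alcohol dehydrogenase used in fermentation under low oxygen. adh1 stood at 53247 ± 5650 normalized counts at 25 °C and 29188 ± 2253 at 10 °C, a log2 change of -0.87 ± 0.21 (SE), with no overlap between the libraries, but it missed the threshold (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.0657). ald1 lies on chromosome 3 at 168340693 to 168343022 (plus strand) and adh1 on chromosome 1 at 278821306 to 278824958 (minus strand), in the coordinates of B73 RefGen_v4.

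ald1 was the only 1 of the 76 tested genes past the threshold in B73, at an adjusted p of 0.0499 (edgeR quasi-likelihood, Benjamini-Hochberg), and 8 genes had an unadjusted p under 0.05. The ald1 cold response in B73 lay at the threshold, and its call was lost with median-ratio scaling, with TMM factors and without the mean-variance trend (0 genes each). It was also lost without B73 25 °C replicate 1, 2 or 3 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0904, 0.167 and 0.209), B73 10 °C replicate 1 or 3 (0.0545 and 0.121), Mo17 25 °C replicate 2 (0.083) or Mo17 10 °C replicate 3 (0.0623), within a range of 0.000157 to 0.209 over all alternatives. Without B73 10 °C replicate 1 the gene called was ARF11, an auxin response factor, at a log2 change of -0.79 ± 0.17 (SE). Of the 8 genes with an unadjusted p under 0.05, 6 had lower values at 10 °C: ald1, adh1, arf1, aldh2, AI812156 and aprl6. The remaining members were ACR4, at a log2 change of 0.35 ± 0.12 (SE), and aprl1, at 2.52 ± 0.89 (SE). The value of aprl1 came from a single library, B73 10 °C replicate 1, at 5353 normalized counts against 296.3 and 364.2 in the other 2 libraries of its group. That library also stood apart over all tested genes, correlating at 0.969 and 0.974 with its replicates, which correlated at 0.997 with each other. In 10 of the 76 genes the libraries of the 2 temperatures did not overlap, where chance gives 10% of genes.

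In Mo17, arf1 and a2_1 fell at 10 °C. arf1 encodes an ADP-ribosylation factor, a small GTPase of vesicle transport. It went from 12492 ± 2474 to 7528 ± 469 normalized counts (mean ± SD, n = 3 each), a 1.66-fold decrease with a log2 change of -0.73 ± 0.14 (SE; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0168). a2_1, annotated as a membrane protein with glycosyltransferase activity and otherwise of unknown function, went from 9632 ± 3048 to 5032 ± 450 normalized counts, a 1.91-fold decrease with a log2 change of -0.94 ± 0.20 (SE; edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0257). For both genes, all 3 libraries at 10 °C lay below all 3 at 25 °C. arf1 lies on chromosome 5 at 3149220 to 3151838 (minus strand) and a2_1 on chromosome 9 at 53472170 to 53476145 (plus strand).

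These were the 2 genes past the threshold among the 76 in Mo17, and 17 genes had an unadjusted p under 0.05. Below the threshold, Mo17 gave ald1 at a log2 change of -0.74 ± 0.22 (SE) and adh1 at -0.63 ± 0.21 (SE), with adjusted p of 0.0829 and 0.0906 (edgeR quasi-likelihood, Benjamini-Hochberg). abc1, named as a homolog of a yeast ABC gene, had a log2 change of 0.47 ± 0.12 (SE) and ACR4, annotated to the regulation of amino acid metabolism and the response to cytokinin, 0.42 ± 0.12 (SE), and neither passed. With median-ratio scaling 2 genes were called higher and 2 lower, with quantile normalization abc1 and AI691686 higher and aldh2 lower, and a fit of the 6 Mo17 libraries alone called none. Both arf1 and a2_1 lost their calls with quantile normalization, and a2_1 also with the replicate block. The arf1 cold response in Mo17 and the a2_1 cold response in Mo17 were both lost without Mo17 25 °C replicate 2 (adjusted p = 0.0817 and 0.0896), Mo17 25 °C replicate 3 (0.0769 and 0.102), Mo17 10 °C replicate 1 (0.102 for each) or Mo17 10 °C replicate 3 (0.0719 for each), and a2_1 also without Mo17 10 °C replicate 2 (0.0668; edgeR quasi-likelihood, Benjamini-Hochberg). Over all alternatives the adjusted p ran from 6.49e-05 to 0.199 for arf1 and from 0.000331 to 0.212 for a2_1. In 21 of the 76 genes the libraries of the 2 temperatures did not overlap, where chance gives 10%.

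**Figure D1:**
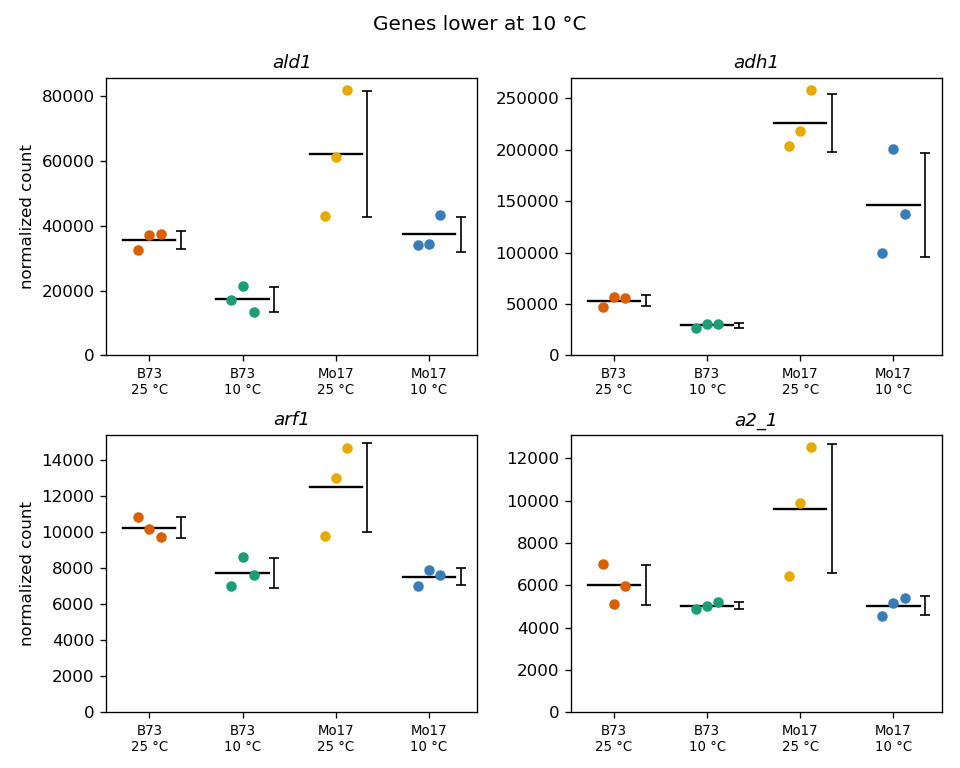
Normalized counts (vertical axes, each starting at 0) of 4 genes in the 4 groups, with 1 point per library, a horizontal line at the mean of 3 libraries and an error bar of 1 SD beside it. In B73, ald1 averaged 35643 at 25 °C and 17308 at 10 °C, and in Mo17, arf1 averaged 12492 and 7528.

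Averaging the 2 lines in the same model, a contrast added after the data were seen, gave 8 genes that changed with temperature, 7 of them lower at 10 °C. The largest decrease was that of ald1, at a log2 change of -0.89 ± 0.16 (SE), followed by adh1 at -0.75 ± 0.15 (SE). aprl6 had a log2 change of -0.64 ± 0.15 (SE). Its symbol refers to adenosine phosphosulfate reductase, and its annotation to protein disulfide isomerase activity and protein folding in the endoplasmic reticulum. a2_1 fell at -0.60 ± 0.14 (SE), arf1 at -0.57 ± 0.10 (SE), aldh2, which encodes a mitochondrial aldehyde dehydrogenase, at -0.51 ± 0.14 (SE), and AI812156, annotated as a subunit of the Elongator complex, at -0.35 ± 0.08 (SE). ACR4 was the 1 gene that rose, at 0.39 ± 0.09 (SE). Adjusted p ran from 0.00542 for arf1 and ald1 to 0.032 for aldh2 (edgeR quasi-likelihood, Benjamini-Hochberg). With quantile normalization abc1 was called higher and ald1, aldh2 and arf1 lower, and the calls of ACR4, adh1, aprl6, a2_1 and AI812156 were lost. Median-ratio scaling ended those of AI812156 and aldh2. The aldh2 cold response averaged over both lines was also lost with a replicate block and without B73 25 °C replicate 1 or 3 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0988 and 0.0985), B73 10 °C replicate 1 or 3 (0.0548 and 0.0916), Mo17 25 °C replicate 1 or 3 (0.0682 and 0.0677) or Mo17 10 °C replicate 1 or 2 (0.0764 and 0.0524). Over all alternatives the adjusted p of aldh2 ran from 0.0037 to 0.0988. The a2_1 cold response averaged over both lines was lost without B73 25 °C replicate 1 (0.0512), and the AI812156 cold response averaged over both lines without B73 25 °C replicate 3 (0.0521) or B73 10 °C replicate 3 (0.0518).

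Whether the lines responded differently to 10 °C was tested as the interaction of line and temperature. No gene passed (edgeR quasi-likelihood with Benjamini-Hochberg adjustment, smallest adjusted p = 0.432), with 6 genes at an unadjusted p under 0.05, and limma and DESeq2 also called 0. A difference between the lines was therefore not shown for the genes called in 1 line. For ald1 the log2 change was -1.04 ± 0.22 (SE) in B73 and -0.74 ± 0.22 (SE) in Mo17. For arf1 it was -0.40 ± 0.13 (SE) in B73 and -0.73 ± 0.14 (SE) in Mo17. The smallest unadjusted p belonged to abc1, with an interaction of 0.55 ± 0.17 (SE) on the log2 scale, and to AI691686, with 0.59 ± 0.19 (SE). Quantile normalization called both of these genes. Of the 76 genes, 49 had the same sign of change in both lines, 31 lower and 18 higher at 10 °C, and the changes correlated at a Pearson r of 0.248 and a Spearman rho of 0.354 across genes, which are not independent replicates. Without B73 10 °C replicate 1 the same sign was seen for 41 genes, and the correlations were 0.231 (Pearson) and 0.199 (Spearman). No gene was called in both lines by the edgeR test on all 12 libraries. DESeq2 called ald1 and adh1 lower in both lines, array weights and the fit without Mo17 25 °C replicate 1 called ald1 in both, and the fit without Mo17 10 °C replicate 2 called adh1 in both.

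Far more genes separated the lines than the temperatures. At 25 °C, acpt1, annotated as an acyl carrier protein of fatty acid synthesis, was 5.79-fold higher in Mo17, at 2326 ± 346 normalized counts against 402 ± 58.5 in B73 (mean ± SD, n = 3 each; log2 change 2.53 ± 0.19, SE). adh2, the other alcohol dehydrogenase of the table, was 23.6-fold higher in Mo17 (log2 change 4.56 ± 0.71, SE), at 2217 ± 1561 against 93.7 ± 13 normalized counts. Its 3 Mo17 libraries ranged from 416.9 to 3208. aldh2 was 5.03-fold lower in Mo17, at 2100 ± 111 against 10564 ± 2130 normalized counts (log2 change -2.33 ± 0.20, SE). The alternative oxidases, mitochondrial enzymes that pass electrons to oxygen outside the cytochrome pathway, went in opposite directions. aox1 was 43.8-fold higher in Mo17 (log2 change 5.45 ± 0.71, SE) and aox1_1 was 12.8-fold lower (-3.67 ± 0.26, SE).

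In all, 47 of the 76 genes passed the threshold between the lines at 25 °C, 28 higher and 19 lower in Mo17, and 53 genes had libraries that did not overlap, where chance gives 10%. The other large increases in Mo17 were those of am1, a regulator of meiosis, at a log2 change of 5.92 ± 0.97 (SE), and ae1_1, a starch branching enzyme, at 3.11 ± 0.31 (SE). am1 stood at 18.4 ± 19.7 normalized counts in B73, with 1 library at 0, and its size was uncertain: the am1 line difference at 25 C was 7.14 without B73 25 °C replicate 3. The other large decreases were those of abp4, an auxin-binding protein, at -2.05 ± 0.27 (SE), aoc1, an allene oxide cyclase of jasmonate synthesis, at -1.80 ± 0.23 (SE), and adk1, an adenylate kinase, at -1.19 ± 0.14 (SE). The adjusted p of these genes ran from 5.98e-07 for aox1_1 to 0.000276 for am1 (edgeR quasi-likelihood, Benjamini-Hochberg). The increases were smaller with quantile normalization, which was run on log2(FPKM + 1), a scale that lessens the change of low genes, at 2.39 for am1, 3.54 for aox1, 3.01 for adh2, 1.16 for ae1_1 and 1.64 for acpt1. The split of 28 higher and 19 lower depended on the scaling, with 26 and 27 under TMM, 27 and 22 under median-ratio factors and 18 and 23 under quantile normalization. These scalings lowered the median log2 difference of the tested genes from 0.17 to -0.09, 0.03 and -0.09, and 5 called genes reached 0 or changed sign under at least 1 of them (act2, adh1, akin1, ald1 and AR3). Of these, adh1 and AR3 reached 0, under quantile normalization, which gives genes of equal rank in every library the same value. For such abundant genes the 0 is fixed by the method and does not test the difference.

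**Figure D2:**
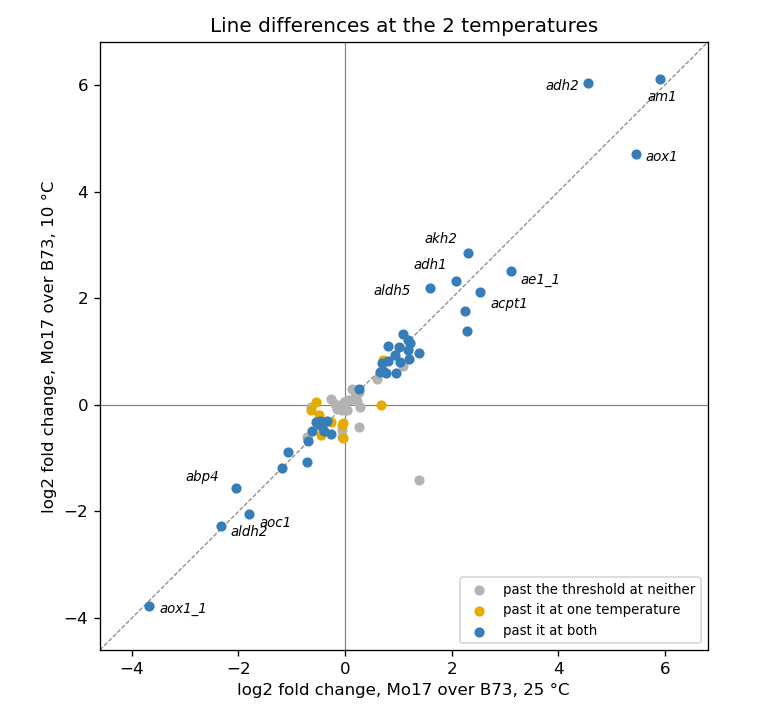
Log2 fold change of Mo17 over B73 for the 76 tested genes at 25 °C (horizontal axis) and at 10 °C (vertical axis), coloured by whether the adjusted p was under 0.05, with the line of equality dashed. The 43 genes past the threshold at both temperatures have the same sign at each; aox1_1 lies close to the dashed line at -3.67 and -3.78, and adh2 lies off it at 4.56 and 6.04.

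At 10 °C the line differences were much the same. adh2 was 65.6-fold higher in Mo17, at 2321 ± 1082 against 35.3 ± 12 normalized counts (mean ± SD, n = 3 each; log2 change 6.04 ± 0.77, SE). am1 was higher at a log2 change of 6.11 ± 0.97 (SE), aox1 at 4.70 ± 0.69 (SE), akh2, a bifunctional enzyme of aspartate-derived amino acid synthesis, at 2.85 ± 0.42 (SE) and ae1_1 at 2.51 ± 0.30 (SE). aox1_1 was lower in Mo17 at -3.78 ± 0.26 (SE), aldh2 at -2.27 ± 0.20 (SE), aoc1 at -2.05 ± 0.24 (SE), abp4 at -1.56 ± 0.27 (SE) and adk1 at -1.19 ± 0.14 (SE). With quantile normalization the increases were 4.18 for adh2, 2.49 for am1, 2.88 for aox1, 1.15 for akh2 and 0.99 for ae1_1. The adjusted p of these 10 genes ran from 4.71e-07 for aox1_1 to 0.000395 for abp4 (edgeR quasi-likelihood, Benjamini-Hochberg).

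At 10 °C 49 of the 76 genes passed, 28 higher and 21 lower in Mo17, and 43 genes passed in the same direction at both temperatures, 27 higher and 16 lower, where independent lists would share 10.3 and 5.25. The log2 differences at the 2 temperatures correlated at a Pearson r of 0.949 and a Spearman rho of 0.881 across genes, which are not independent replicates, and the 2 comparisons share no library. TMM factors gave 22 higher and 32 lower and moved the median log2 difference of the tested genes from 0.06 to -0.26. With median-ratio factors that median was -0.08 and with quantile normalization -0.07, and 4 called genes reached 0 or changed sign under at least 1 scaling (akin1, amyb5, aos1 and AR3). The value of 0 was that of AR3, again fixed by quantile normalization.

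Further genes, several of them members of the same families, were singled out after their values were seen, and differences between family members were not tested. adh1 was 4.25-fold higher in Mo17 at 25 °C (log2 change 2.09 ± 0.22, SE) and 5.01-fold at 10 °C (2.32 ± 0.22, SE). Its difference at 25 °C went to 0 under quantile normalization, which gives every library the same highest values. Among the actins, act1 was higher in Mo17 at both temperatures (log2 change 1.22 ± 0.07 at 25 °C and 1.16 ± 0.07 at 10 °C, SE), while act2 was lower (-0.27 ± 0.11 and -0.55 ± 0.11, SE), and act2 turned to 0.09 at 25 °C in the least favourable of the scalings. Of the mitochondrial ADP/ATP carriers, ANT1 was higher in Mo17 (0.94 ± 0.16 at both temperatures, SE), but it was not called with quantile normalization, and ANT2 did not pass at 0.08 ± 0.15 (SE) at each. In the jasmonate pathway aos1, an allene oxide synthase, was higher in Mo17 (1.19 ± 0.21 at 25 °C and 0.86 ± 0.21 at 10 °C, SE) and aoc1 was lower, but aos1 turned to -0.21 at 10 °C under another scaling. Of the subunits of ADP-glucose pyrophosphorylase, which makes the substrate of starch synthesis, the large subunit AGPLS3 was higher (0.69 ± 0.11 at 25 °C, SE) and the small subunit Agpsemzm lower (-0.47 ± 0.08 at 25 °C, SE) in Mo17, each with the same sign under all 4 scalings. AGP2, annotated like both to starch and sucrose metabolism, was not called at either temperature. Its log2 change was 0.21 at 25 °C and 0.20 at 10 °C, and its sign depended on the scaling. Members of such families can share reads, so the division of counts between adh1 and adh2, among the aox genes, and between act1 and act2 or ANT1 and ANT2 is uncertain.

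**Figure D3:**
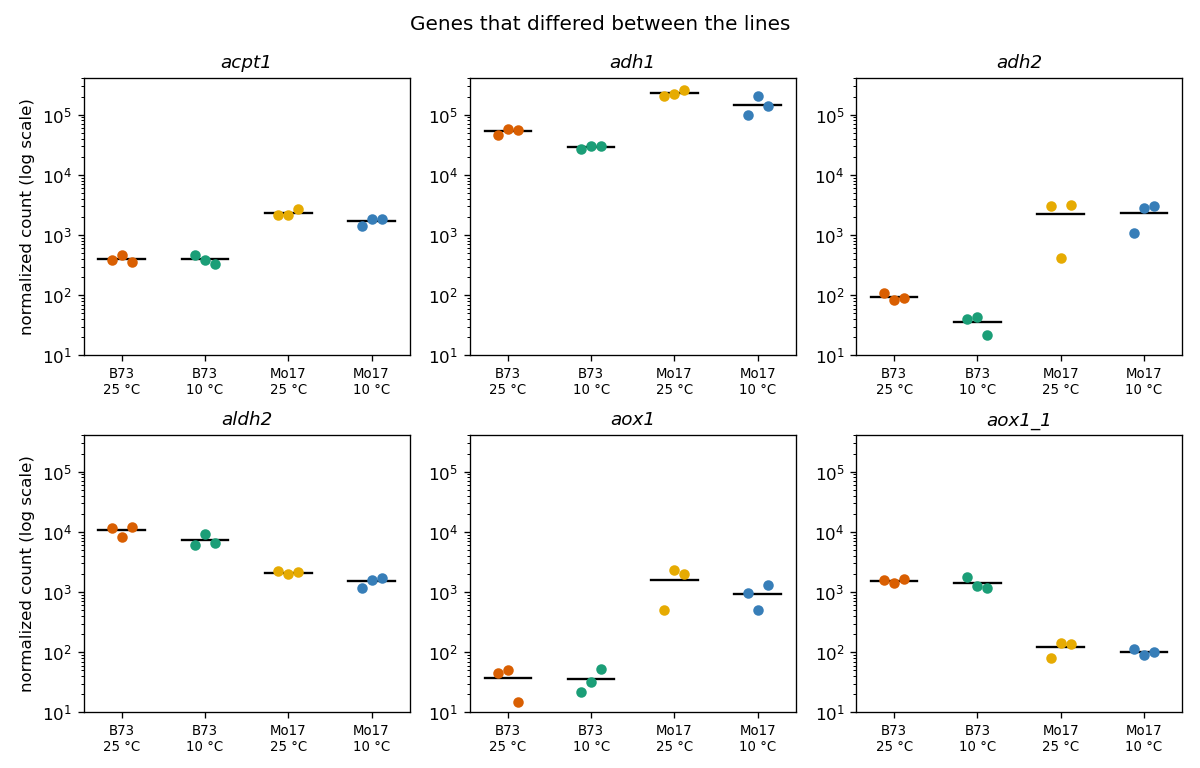
Normalized counts (vertical axes, log scale) of 6 genes in the 4 groups, with 1 point per library and a horizontal line at the mean of 3 libraries. aox1 and aox1_1 change places between the lines, and adh2 averaged 2217 in Mo17 and 93.7 in B73 at 25 °C.

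Of the gene lists fixed before the data were examined, 2 had at least 5 tested members. In the list of auxin, cytokinin, ethylene, jasmonate and brassinosteroid genes, with 7 tested members, none changed at 10 °C in B73 and 1, arf1, fell in Mo17, the same when adjusted over the list alone. arf1, an ADP-ribosylation factor, entered that list by symbol and is not an auxin response factor. Of the other members, ARF16 had log2 changes of 0.09 ± 0.08 (SE) in B73, and abp1, an auxin-binding protein, 0.09 ± 0.09 (SE) in B73 and -0.14 ± 0.09 (SE) in Mo17. Between the lines 2 members of the list were higher in Mo17 at each temperature (abp1 and aos1) and 1 was lower (abp4), again with the same counts adjusted over the list alone. The list as a set was not called by camera in any of the 5 planned comparisons (smallest adjusted p = 0.593). Fry, which tests whether members move 1 way on balance, called the list higher in Mo17, with adjusted p of 0.00724 at 25 °C and 0.0377 at 10 °C. Unlike camera, fry does not set a list against the other genes. Of all tested genes, 61.8% at 25 °C and 64.5% at 10 °C were called between the lines, so this call is not particular to the list. In the cold comparison of Mo17 the median member stood at 0.06 and the mean at -0.04, and fry called a change in either direction (adjusted p = 0.0391).

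In the list of mitochondrial respiration, with 5 tested members, none passed at 10 °C in either line, also when adjusted over the list alone. aldh2 had log2 changes of -0.54 ± 0.19 (SE) in B73 and -0.48 ± 0.20 (SE) in Mo17, aox1_1 -0.15 ± 0.23 (SE) and -0.25 ± 0.24 (SE), and ANT2 0.08 ± 0.15 (SE) in each. Between the lines aox1 and ANT1 were higher in Mo17 and aldh2 and aox1_1 lower at both temperatures, the same 2 and 2 adjusted over the list alone. Camera did not call the set between the lines (adjusted p = 0.314 at 25 °C and 0.315 at 10 °C), with the median member at 0.08 on the log2 scale and the test downward at each. Fry called it downward, with adjusted p of 0.003 and 0.00423, and also as changed in either direction. These calls are likewise not particular to the list, since most tested genes were called between the lines. No list was called by camera with an estimated correlation either.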

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

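The tests of scaling, read mapping, the alternative oxidases and the library that stood apart were chosen after the results were seen. The 7 values that follow belong to genes outside the filter on low values, tested in a fit without that filter, and they stand out because their signal differed between the lines in data that the comparisons above left out. ACO31, an aminocyclopropane carboxylate oxidase of ethylene synthesis, was higher in Mo17 at a log2 change of 6.10 at 25 °C and 3.90 at 10 °C. The size of these changes is uncertain, since the B73 level of ACO31 came mainly from 1 library at each temperature. In B73 it was listed at 0 in replicates 1 and 3 and at 9.1 normalized counts in replicate 2 at 25 °C, and at 18, 0 and 3.74 at 10 °C, while Mo17 averaged 212 at 25 °C. an2, which encodes a copalyl diphosphate synthase, was higher in Mo17 at 2.33 at 25 °C and 2.57 at 10 °C on the log2 scale. AGA2, an alkaline alpha-galactosidase, was higher at 3.07 at 25 °C, a size that rests largely on B73 replicate 3, as the B73 libraries stood at 0, 4.55 and 20.5 normalized counts. aox3, the remaining alternative oxidase, averaged 21.1 normalized counts in Mo17 at 25 °C and was listed at 0 in all B73 libraries. AGAMOUS averaged 14.3 normalized counts in Mo17 at 10 °C and was likewise listed at 0 in B73, and in Mo17 10 °C replicate 3. All of these genes had a mean FPKM below 1 in each group, their adjusted p ran from 0.00201 to 0.0438 (edgeR quasi-likelihood, Benjamini-Hochberg), and no explanation was tested for them.

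Many genes differed between the lines, and reads of Mo17 were counted on a B73 genome, so loss of Mo17 reads and a wrong scaling between the lines are technical explanations. Loss of reads at a gene cannot raise the count of that gene in Mo17, and over 4 scalings at least 17 genes were called higher in Mo17 at both temperatures. All 4 scalings are relative, however, so that reads lost at other genes could raise the remaining ones. The count of higher genes therefore cannot decide whether loss of reads contributed. A single wrong factor between the lines would leave calls in 1 direction, and at least 16 genes were called lower and 17 higher at both temperatures in each of the 4 scalings, which argues against that as the whole source. For the 16 genes called lower in Mo17 at both temperatures, sequence differences between the lines were not measured, so that loss of reads and lower expression cannot be told apart.

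In Mo17 aox1 was higher and aox1_1 lower, at 1596 ± 972 and 121 ± 34.3 normalized counts at 25 °C against 36.8 ± 19.1 and 1546 ± 99 in B73 (mean ± SD, n = 3). A candidate explanation is that reads of 1 locus were counted at the other in Mo17, where aox1_1 would then rise and fall with aox1 and the sum would not differ between the lines. Over the 6 Mo17 libraries the correlation was 0.946 (Pearson, exact permutation p = 0.00972, adjusted for 2 relations 0.0194; Spearman rho 0.943, exact permutation p = 0.0167, adjusted 0.0334), and it was 0.706 without the 2 libraries farthest from the median of aox1, while in the 6 B73 libraries it was -0.62 (exact permutation p = 0.194; Spearman rho -0.771, exact permutation p = 0.103) and 0.03 without 2. The sum of the 3 aox genes had line differences of 0.14 ± 0.45 (SE) at 25 °C and -0.46 ± 0.45 (SE) on the log2 scale at 10 °C, unadjusted p 0.767 and 0.328. Shared reads therefore remain open, and so do a joint control of both genes and a biological difference between the lines, since aox1_1 was not a fixed share of aox1 (6.14% to 18% over the Mo17 libraries).

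B73 10 °C replicate 1 stood apart from its replicates. It held 5353 normalized counts of aprl1 against 296.3 and 364.2 in its replicates, and 1989 of ARF11 against 373.2 and 391.3. Admixed Mo17 material would raise aox1, adh2 and am1, and their median excess over the replicates was -0.0214 of the Mo17 level, which argues against it. Lower depth is argued against by a relative depth that differed by -1.93% from the mean of the replicates. A difference between the seeds or another handling difference stays open and was not tested.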

How the results depend on the processing

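The alternatives with TMM factors, limma on log2(FPKM + 1) and DESeq2, every alternative of the averaged cold contrast and most of the count called in both lines were chosen after seeing the data. The 20 named line differences kept their direction and side of the threshold in all 470 alternative values, though not their size. They had been chosen as the largest changes past the threshold without overlap, so this does not carry over to the other line calls. Counts between the lines ran from 37 to 53 at 25 °C and from 35 to 54 at 10 °C, within 1.5 times of the reported 47 and 49. The genes behind these counts changed more. Under all 4 scalings (relative depth, median-ratio, TMM and quantile), 32 of the 47 genes stayed called at 25 °C, 16 higher and 16 lower in Mo17. At 10 °C 29 of the 49 stayed called, 17 higher and 12 lower. The cold calls were fragile. In B73 1 gene became 0 with median-ratio scaling, without the mean-variance trend and with TMM, and 2 (ald1 and adh1) with DESeq2, with only the 6 libraries compared and with a replicate block. Leaving out single libraries gave 0 to 2, and 0 without any of B73 25 °C replicates 1, 2 and 3, B73 10 °C replicate 3, Mo17 25 °C replicate 2 or Mo17 10 °C replicate 3, and 2 without Mo17 10 °C replicate 1 or 2. In Mo17 2 genes became 4 with median-ratio scaling, 5 without the trend, 11 with array weights, 1 with the replicate block, 0 with only the 6 libraries compared and 9 with DESeq2. Leaving out single libraries gave 0 to 5, with 5 without Mo17 25 °C replicate 1 or B73 10 °C replicate 1, and 0 without Mo17 25 °C replicate 2 or 3 or Mo17 10 °C replicate 1 or 3, while without Mo17 10 °C replicate 2 1 of the 2 calls was another gene. The interaction gave 2 genes and the averaged contrast 4 with quantile normalization, and the averaged contrast 6 to 9 when libraries were left out. The reported 0 genes called in both lines became 2 (ald1 and adh1) with DESeq2 and 1 (ald1) with array weights, and 0 to 1 when libraries were left out, with ald1 without Mo17 25 °C replicate 1 and adh1 without Mo17 10 °C replicate 2. The cause was not tested. Fits without a library have fewer samples.

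The replicate block left 46 and 43 line calls and no interaction. Replicate numbers did not pair the libraries throughout, since the correlation of same-numbered deviations ran from -0.435 to 0.444 and exceeded 0.1 in 4 of 18 pairs, and 0 libraries matched best with their own number in every other group.

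Some gene values near 0, none of them called, turned sign. The ANT1 cold response in B73 (0.01) became -0.0154 with log2(FPKM + 0.1), -0.0152 with log2(FPKM + 1), -0.00214 with quantile normalization, -0.10 with array weights and -0.00437 with the replicate block, and ran from -0.22 to 0.17 as libraries were left out, below 0 without B73 25 °C replicate 1 or 3 or B73 10 °C replicate 1. ANT2 in B73 ran from -0.10 to 0.23, below 0 without B73 25 °C (-0.01) or 10 °C replicate 1. The hormone list changed direction at an adjusted p of 0.972 by fry in B73 and 0.719 with quantile normalization between the lines at 10 °C, where fry had called it higher in Mo17, and in the averaged contrast at 0.399 by fry and 0.790 with quantile normalization. Of 477 values of genes named with temperature in 1 line, the 10 above turned, 431 stayed, 24 lost the threshold and 12 passed it. In the averaged contrast 164 of 183 stayed and 19 lost it.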

Other observations

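Tests of annotation terms with at least 5 members, and the split of glycolysis genes, were chosen after the data were seen. The 6 tested genes annotated to glycolysis and gluconeogenesis (acpt1, adh1, adh2, ald1, aldh2 and AR3) were lower at 10 °C as a set in the averaged cold contrast, with 3 called lower (adh1, ald1 and aldh2) and 0 higher (limma's camera with preset correlation, Benjamini-Hochberg adjusted over 22 terms, adjusted p = 0.0106; fry adjusted p = 0.0129). With an estimated correlation the call was lost (adjusted p = 0.398). Without adh1 and ald1, fry did not call the other 4 genes, with an unadjusted p of 0.0606 against 0.00235 for all 6. In B73 alone the set was called by camera (adjusted p = 0.0106), but not with an estimated correlation (adjusted p = 0.531) or by fry (adjusted p = 0.0752). In Mo17 it was called as lower by neither camera (adjusted p = 0.112) nor fry (adjusted p = 0.0658), and the interaction was not called (adjusted p = 0.878). Fry's test for a change in either direction called the set in B73 (adjusted p = 0.0311) and in Mo17 (adjusted p = 0.0493). This was not particular to glycolysis. Among other terms, the same fry test called cytosol (adjusted p = 0.0146 in B73 and 0.00073 in Mo17) and cytoplasm (0.00367 and 0.00522). acpt1 carries an acyl carrier annotation beside its glycolysis term, and AR3 is an uncharacterized protein with the same term. Fry also called the terms cytoplasm and Golgi apparatus as lower at 10 °C in B73 (adjusted p = 0.0257 for each) and in Mo17 (adjusted p = 0.0248 for each), where camera did not; their members include adh1, with ald1 in the former and arf1 in the latter. Fry called integral component of membrane lower in Mo17 (adjusted p = 0.0248) and not in B73 (0.614). In the averaged contrast fry called all 3 of these terms lower, and also plasma membrane (adjusted p = 0.0188), zinc ion binding (0.0129) and response to salt stress (0.027), and camera called none of these 6 terms. Plasma membrane, zinc ion binding and response to salt stress all hold adh1 and adh2, and adh1 was the only member of each that was called, so they are not independent of each other.

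The 5 tested genes of starch and sucrose metabolism (ae1_1, AGP2, AGPLS3, Agpsemzm and amyb5) gave 0 calls with temperature. Between the lines at each temperature 3 were higher in Mo17 (ae1_1, AGPLS3 and amyb5) and 1 lower (Agpsemzm), and fry called the set higher in Mo17 (adjusted p = 0.000571 at 25 °C and 0.000803 at 10 °C) while camera did not (0.774 and 0.760). That call was not particular to starch metabolism, since fry called many of the other terms between the lines. Among them was cytoplasm, higher in Mo17 with a fry adjusted p of 1.07e-06 at 25 °C and 9.46e-07 at 10 °C. amyb5, a beta-amylase, was 4.86-fold higher in Mo17 at 25 °C and 2.62-fold at 10 °C, sizes that depended on the processing. Over 4 scalings its log2 difference fell as low as 0.35 at 25 °C, called in 3, and changed sign at 10 °C, called in 2. Quantile normalization, 1 of the 4, also used log2(FPKM + 1), which lessens the change of low genes such as amyb5. The effects of scaling and of that scale were not separated. Of the 7 tested genes annotated to protein disulfide isomerase activity, aprl3 to aprl9, 1 (aprl6) was lower at 10 °C in the averaged contrast, 2 were higher and 2 lower in Mo17 at 25 °C (aprl5 and aprl6, and aprl4 and aprl8), and camera did not call the set. Fisher's exact test over the 6 terms with at least 10 tested members gave an adjusted p of 1 for each in both cold comparisons, where 1 and 2 genes were called.

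The other lists fixed before the data were examined had at most 2 tested members, and no tested member was called with temperature in either line. These members were ANAC076, a NAC transcription factor, apx2, an ascorbate peroxidase, amyb5, aap1, a peptidase, a4, a glycosyltransferase, and ANT1 and ANT2 as membrane carriers. The lists of endosperm markers, abscisic acid and gibberellin had 1 member each in the table (ae1, aba1 and an1) and none past the filter. The lists of late embryogenesis proteins, heat shock proteins, storage proteins, leaf photosynthesis genes, AP2/ERF factors, thioredoxins, lipid metabolism, cell wall, calcium signalling, receptor kinases, histones and ribosomal proteins had 0 members among the 99 genes, so that admixture of other tissues was not assessed.

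Other groupings of the libraries were tried, as planned for all comparisons but the averaged contrast, which was added after the data were seen. Among the 10 splits of the 6 libraries at each temperature, the split by line gave 48 genes at 25 °C and 40 at 10 °C, the highest other split gave 0, and 1 split, the real one, gave as many. In fits of the 6 libraries of a line, the split by temperature gave 2 genes in B73 and the highest of the other 9 splits gave 0, so that 1 of 10 splits reached it. In Mo17 the real split gave 0, and so did the others, so that 10 of 10 reached it. In each of these 4 comparisons the 10 splits are too few for a share under 0.05. For the averaged contrast 100 of the 200 ways to assign temperature within the lines were fitted, the real one included. The real assignment gave 8 genes, 2 of the 100 gave at least as many, and the highest other gave 10. So high a count was thus rare among the assignments, but chance is not excluded, because the contrast was chosen after the data were seen. The share concerns the number of calls and not any of the 8 genes. The assignment with 10 genes kept the Mo17 labels and exchanged 1 B73 library of each temperature, which left most of the real split in place. For the interaction the real assignment gave 0 genes, 100 of 100 gave at least as many, as they must, and the highest other gave 10, so that this count tests nothing.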
